A study of Mus musculus with 18 samples.

How the data were processed

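The series holds 18 libraries of mouse medial prefrontal cortex, 9 per diet, prepared from total RNA by a method biased to the 3' end and sequenced as single ends on a HiSeq 2500, per the labels. The deposited values are whole-number read counts per gene, 1 file per library, over 54547 Ensembl gene identifiers. The submitters' processing notes name FastQC 0.11.8, Bowtie2 2.3.4.3, HTSeq 0.11.0, DESeq2 1.10.1 and R 3.5.1, and the builds mm10 and GRCm38.p6. The role of each tool, the strand setting, the feature counted, the annotation release and any use of random bases to remove duplicates are not given in the sources used here. The animals are separate per the numbers in their titles, but the labels state nothing on cages, litters or sessions.

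The strand and feature used were examined on the values. Of 371 protein-coding genes nested in another gene on their own strand none had a count, while 351 of 534 nested only in a gene on the other strand had counts. Genes spanning over 500 kb held 12.4% of counts. The counts therefore behave as strand-specific counts over whole gene bodies, in which reads shared by overlapping genes on a strand are dropped. Of the listed genes, 11 are overlapped over more than 50% of their span, and 8 of these have 0 counts in all libraries. A count of 0 in Itgam, Irf8 or Tubb3 thus does not show that the gene was silent. Identifiers were matched to GENCODE M21, 53706 of them without regard to version, and the 841 unmatched hold 0.028% of counts.

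Counts per library ran from 990136 to 1742680, so that 1 CPM is about 1 to 2 counts. Pairs of libraries differed by more than sampling noise, with a lowest chi-square per degree of freedom of 1.129 over genes with at least 20 counts in a pair, and none was treated as a duplicate. Genes were tested with edgeR 4.0.16 (R 4.3.3) on the counts as deposited, with filterByExpr at its defaults (minimum count 10, minimum total 15), TMM scaling, a robust quasi-likelihood fit and Benjamini-Hochberg adjustment, calling an adjusted p under 0.05. This kept 11051 genes. Fold changes are PLX5622 over control, and log2 CPM carry a prior count of 2. Lists with at least 3 tested genes, the list of sex-linked genes left out (27 of 34), were tested with camera in limma 3.58.1 at a preset correlation of 0.01. Means and sums of lists were compared over all 48620 group assignments. Correlations within a diet were tested over all 362880 orders, in place of the random draws planned. The list of sex-linked genes was used only to check the labels and gave 0 calls, with Kdm5d at -0.15, Eif2s3y at 0.06 and Ddx3y at 0.03 (log2).

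Groups come from the titles. Replicate numbers do not overlap between the diets, so no paired fit was made. The design, the 34 lists, the rule for named genes and the alternatives were fixed before the data were examined. The rule names the 12 genes per direction with the largest change among called genes with a mean of at least 10 counts, a fixed set of genes reported whatever their result, and up to 3 tested genes with the smallest p from each list. Some genes that the rule names are not reported here. Arc, Fos, Nr4a1, Btg2, Egr4 and Homer1, the lower genes outside the lists, and the tests on animal numbers were chosen after values were seen. The alternatives were DESeq2 1.42.0, limma-voom, other scalings and count filters, 1 surrogate variable from sva 3.50.0, thinning to the smallest library, other thresholds, and leaving out each library. A covariate for the position of the animal number within its diet, and a fit without control 8 and PLX5622 28, were added after seeing the data.

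The fit was tested on simulated counts for the comparison of PLX5622 with control, over 10937 genes. It recovered 40% of genes changed 1.25-fold, 78% at 1.5-fold, 92% at 2-fold and 92% at 3-fold, with 9 false calls among 160. Simulated genes vary independently, which real genes do not, so the absence of list calls in simulated sets without a change does not carry over to the libraries.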

Results

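RNA from the medial prefrontal cortex of C57BL6/J mice was measured in 18 libraries, 9 from animals fed a control diet and 9 from animals fed chow with PLX5622 at 1200 mg/kg. PLX5622 is an inhibitor of the receptor CSF1R, on which microglia, the resident macrophages of the brain, depend for survival. The labels give the diet for 21 days before every-other-day drinking of 15% ethanol for 44 days. They give tissue taken 24 hours after the last ethanol at postnatal day 100. Whether the diet went on during the drinking is not stated here. The same treatment text stands on all 18 libraries and names PLX5622 on the control samples too, so it does not show what each animal received, ethanol included. An abbreviation in the names of all 18 deposited tables is not explained by the labels. Diet was the only contrast they give, and ethanol was not compared with water. Libraries held 990136 to 1742680 counts, with a median of 1384979. Total counts did not differ between the diets beyond the spread of libraries (exact permutation test, two-sided p = 0.580), and neither did the share of counts from mitochondrial genes, 4.64% ± 0.30 in controls and 4.55% ± 0.39 with PLX5622 (SD, n = 9 each, exact p = 0.579).

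Genes of homeostatic microglia fell in the PLX5622 libraries. Of the 28 genes on that list 18 could be tested and 17 fell, 18 when adjusted over the list alone, and their median log2 fold change was -1.73, which leaves 30.1% of the control level. The mean log2 CPM of the list was 4.89 ± 0.11 in controls and 3.36 ± 0.23 with PLX5622 (SD, n = 9 each, exact permutation p = 4.1e-05, the smallest that the 48620 group assignments can give). Fcrls showed the largest fall among all genes called with a mean of at least 10 counts, -3.43 ± 0.27 (log2, SE), from 16.5 ± 4.5 to 1.41 ± 0.77 CPM (SD, n = 9 each). P2ry12, a purinergic receptor that guides microglial processes, fell by 2.17 on the log2 scale (SE 0.15) from 38.7 ± 3.4 to 8.38 ± 3.91 CPM. Cx3cr1, the fractalkine receptor, fell by 2.06 (SE 0.12) from 50.7 ± 5.9 to 11.96 ± 2.46 CPM, and Csf1r itself by 1.77 (SE 0.13) from 65.2 ± 15.3 to 19.3 ± 4.1 CPM. Tmem119, Selplg, Siglech, C1qa, Laptm5, C1qb, Vsir and Olfml3 fell by 2.14, 2.08, 1.87, 1.81, 1.77, 1.70, 1.60 and 1.49 on the log2 scale. In each of these 12 genes all 9 PLX5622 libraries lay below every control library, and the adjusted p of edgeR's quasi-likelihood test was at most 4.8e-06.

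**Figure D1:**
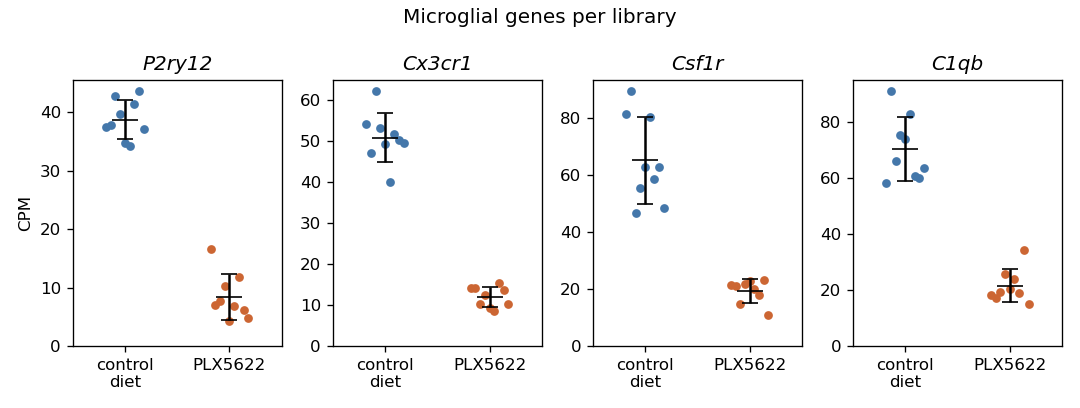
CPM, counts scaled to library size (vertical axes, each from 0) of P2ry12, Cx3cr1, Csf1r and C1qb in the 9 control and 9 PLX5622 libraries. Each point is a library, and the bar gives the mean ± SD of the group. The PLX5622 libraries lie below all control libraries for each gene, with means of 8.38 against 38.7 CPM for P2ry12.

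The Csf1r gene (ENSMUSG00000024621.15) lies on chromosome 18 from 61100598 to 61132149, P2ry12 (ENSMUSG00000036353.13) on chromosome 3 from 59216272 to 59262871, and Cx3cr1 (ENSMUSG00000052336.7) on chromosome 9 from 119901616 to 120069879, in the GENCODE M21 annotation of GRCm38. Counts were summed over whole genes, so no exon or UTR can be named for them.

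Markers of macrophages at the borders of the brain were also lower. None of the 12 genes on that list passed the count filter of the edgeR test, so their CPM were summed, giving 29.5 ± 4.9 in controls and 7.22 ± 3.21 with PLX5622 (SD, n = 9 each, exact permutation p = 4.1e-05, adjusted 0.00034 over 33 lists). These sums rest on 356 and 88 counts. DESeq2, which gave an adjusted p for 18125 genes and so left out fewer at low counts, called 3 of the 12 lower. These were Mrc1 at -3.27, F13a1 at -2.39 and Stab1 at -1.85 (log2, highest adjusted p = 6.3e-05). Mrc1, the mannose receptor, had 65 counts in the controls and 7 with PLX5622, 9.32-fold lower by mean CPM (exact p = 4.1e-05, adjusted 0.00023 over 17 low-count genes). Aif1, which encodes IBA1, had 84 and 42 counts, 2.08-fold lower (exact p = 0.0014, adjusted 0.0034). Itgam was at 0 in every library, and since 99.9% of its span is overlapped by another gene model on its strand, its level cannot be read from these counts. Markers of blood myeloid cells summed to 29.6 ± 60.2 CPM in controls and 16.9 ± 10.0 with PLX5622, which did not differ beyond the spread of libraries (exact p adjusted 0.945). Control 3 held 245 of the 348 control counts, and without it, a choice made after seeing the data, the control mean was 9.62 ± 7.26 CPM (SD, n = 8), below that of PLX5622. Lymphocyte markers summed to 67.0 ± 7.3 and 57.4 ± 5.8 CPM (exact p adjusted 0.020). Most of these sums came from Ighm, an immunoglobulin heavy chain, at 28.2 and 20.4 CPM, and Trbc2, at 36.8 and 35.5 CPM. Cd3e had 2 and 1 counts. Ighm was at -0.44 (log2, edgeR adjusted p = 0.199) and Trbc2 at -0.05. The difference in the sums thus rests mainly on Ighm and does not show a fall of lymphocytes.

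Of the 11051 genes tested, 39 were lower and 5 higher with PLX5622 (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05). Of the 39, 17 stand on a microglial list and 22 on none of the 34 lists, and 21 had groups that did not overlap. The chance of no overlap in a given direction is 1 in 48620 for a single gene with exchangeable libraries. It does not apply to the 21, which were counted among genes already called on the same libraries, and adds no support to them. The lists are short, so absence from them does not show that a gene is not microglial. Lower genes outside the lists, singled out after their values were seen, included the phosphatase gene Inpp5d at -0.93 ± 0.16, the kinase gene Lyn at -0.91 ± 0.17 and the receptor gene Tgfbr1 at -0.80 ± 0.11 (log2, SE). DESeq2 called 65 genes lower. At a mean of at least 50 counts 12 of the 39 remained to be tested, of which 8 were called. The count of higher genes was 7 with DESeq2 and 2 to 13 when 1 library was left out. At a mean of at least 50 counts 2 of the 5 remained to be tested, and 0 genes were called higher.

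Camera called 4 lists lower and 3 higher. Counts as large in either direction arose in 35 and 58 of 100 splits of the 18 libraries, though these splits keep part of the diet difference. The estimated correlation reached 0.64, in the myelinating oligodendrocyte list, against the preset 0.01. Camera's preset p values are therefore likely too small here, and calls with an estimated correlation are given beside them. Complement genes fell through the C1q subunits. Of 12 genes 5 were tested and 3 fell, 4 when adjusted over the list alone, with C1qc at -1.37 ± 0.15 beside C1qa and C1qb above. These 3 also stand on the microglial list. The list was called lower by camera (adjusted p = 9.1e-21) and also with an estimated correlation (adjusted p = 0.00017). The list of disease-associated microglial genes had 11 tested members, none called at the gene level by edgeR, DESeq2 or limma-voom, 4 at an unadjusted p under 0.05 and 3 adjusted over the list alone. Its median was -0.13, with Ctsb at -0.13, Lyz2 at -1.18 and Ctsz at -0.28. Camera called it lower (adjusted p = 0.011), but not with an estimated correlation (adjusted p = 0.0907), while the exact permutation test of its mean log2 CPM passed (difference -0.17, adjusted p = 0.013) and that of its summed CPM, 2165 in controls and 2089 with PLX5622, did not (adjusted p = 0.154). The list of CSF1R ligands and related kinases was called lower by camera (adjusted p = 0.039) through Csf1r, its only called member, and not with an estimated correlation (adjusted p = 0.0907). Its mean log2 CPM differed by -0.20 (exact permutation p adjusted 0.0026). Its median log2 fold change was -0.0005, with 4 members negative and 4 positive, so the mean repeats the fall of Csf1r. The ligands Csf1 and Il34 were at 0.01 ± 0.17 and -0.01 ± 0.09 (log2, SE), Kit at 0.17, Pdgfrb at -0.22 and Pdgfra at 0.01.

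Immediate-early genes, which neurons induce within minutes of activity, were higher in the PLX5622 libraries. All 12 tested members had positive values, 2 rose at the gene level by edgeR, 2 by limma-voom and 5 by DESeq2, and 10 when adjusted over the list alone, with a median of 0.60 (log2). Fosb rose by 0.86 ± 0.20 (log2, SE) from 8.92 ± 4.17 to 16.5 ± 4.1 CPM (SD, n = 9 each, adjusted p = 0.016) and Junb by 0.59 ± 0.13 from 22.5 ± 5.0 to 34.3 ± 8.7 CPM (adjusted p = 0.015). Dusp1 was at 0.65 ± 0.17 (edgeR adjusted p = 0.164, DESeq2 0.016). The list was called by camera (adjusted p = 9.1e-21) and with an estimated correlation (adjusted p = 0.012), and its mean log2 CPM was 4.74 ± 0.29 in controls and 5.30 ± 0.34 with PLX5622 (exact permutation p = 0.0029, adjusted 0.013). The list mean followed the animal number of the labels in controls, with a Pearson's r of 0.95 (exact p = 0.00017, adjusted 0.0091 over 54 relations) and a Spearman's rho of 0.97 (exact p = 0.00017, adjusted 0.0089). With PLX5622 r was 0.86 (exact p = 0.0035, adjusted 0.064) and rho 0.85 (exact p = 0.0061, adjusted 0.109), which did not pass after adjustment. Without the 2 libraries farthest from the median number r was 0.90 and 0.84. Control numbers run from 2 to 11 and PLX5622 numbers from 25 to 35, so diet and any session tied to the numbers cannot be told apart.

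**Figure D2:**
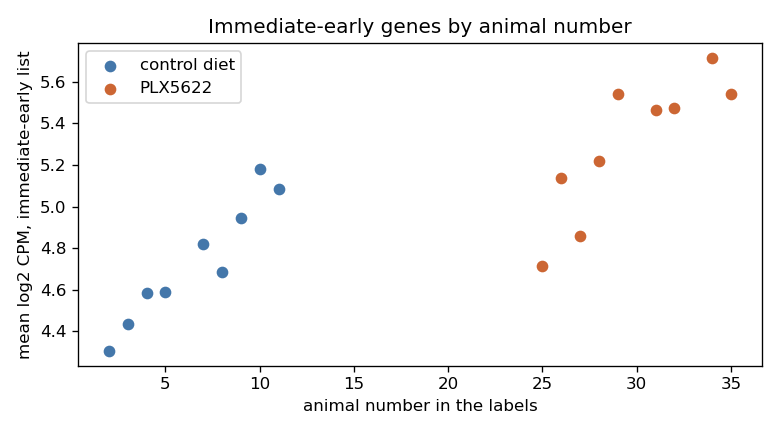
Mean log2 CPM of the tested immediate-early genes (vertical axis) against the animal number in the labels (horizontal axis). Each point is a library, 9 on the control diet and 9 on PLX5622. Pearson's r is 0.95 in controls (exact p adjusted 0.0091) and 0.86 with PLX5622 (exact p adjusted 0.064, which does not pass).

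The other genes called higher were Thrsp, a regulator of lipid synthesis, at 0.71 ± 0.17 (log2, SE), Pcsk1, a prohormone convertase, at 0.54 ± 0.12, and Ndufa1, a subunit of respiratory complex I, at 0.26 ± 0.06, with adjusted p of 0.022, 0.020 and 0.021. All 5 higher calls could be ended by leaving out a single library. Leaving out 1 library ended the call of Fosb for 3 of the 18 libraries (control 2 and 4, PLX5622 35), of Thrsp for 5 (control 2, 9 and 11, PLX5622 26 and 35), of Junb for 1 (PLX5622 34), of Pcsk1 for 7 (control 2, 3, 4, 5 and 7, PLX5622 32 and 34) and of Ndufa1 for 6 (control 3, 4 and 7, PLX5622 28, 29 and 35). The highest adjusted p without 1 library was 0.055, 0.182, 0.052, 0.063 and 0.126 in that order, while the log2 fold changes stayed within 0.77 to 1.01, 0.52 to 0.77, 0.52 to 0.70, 0.47 to 0.62 and 0.22 to 0.30. Other settings also ended calls, of Thrsp with DESeq2 (adjusted p = 0.070) and after thinning (0.288), of Junb after thinning (0.114), of Pcsk1 with limma-voom (0.098), and of Pcsk1 and Ndufa1 at a mean of at least 50 counts (0.073 each). Without control 8 and PLX5622 28, a fit added after seeing the data, Junb was at 0.052 and Pcsk1 at 0.086. A fit with the position of the animal number within its diet was also added after seeing the data. In it Pcsk1 rose by 0.10 ± 0.02 per position (log2, SE, edgeR adjusted p = 0.00041) and Junb by 0.09 ± 0.02 (0.033). Fosb, at 0.11 ± 0.03 per position, was not called (0.152), and neither were Thrsp and Ndufa1 (0.734 and 0.895). The limit given for the immediate-early genes holds for all 5 genes, called on position or not, since diet and any session tied to the numbers cannot be told apart.

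Genes of cholesterol biosynthesis were higher as a list. All 13 tested members had positive values with a median of 0.23 (log2), and 10 passed when adjusted over the list alone. None passed over all genes by edgeR, DESeq2 or limma-voom, and 11 had an unadjusted p under 0.05. Cyp51 was at 0.32 ± 0.08 (SE, adjusted p = 0.077), Sqle at 0.31 ± 0.08 and Hmgcs1 at 0.20 ± 0.06. Camera called the list (adjusted p = 2.2e-14), also with an estimated correlation (adjusted p = 0.0071), and its mean log2 CPM rose from 5.69 ± 0.14 to 5.95 ± 0.10 (SD, n = 9 each, exact permutation p = 0.00025, adjusted 0.0026). Camera also called it upward with the position of the animal number (adjusted p = 0.0021), but not with an estimated correlation (adjusted p = 0.359). The interferon list had 5 tested members, all positive and none called, with Ifi27 at 0.28 and Ifitm3 at 0.46. Camera called this list higher (adjusted p = 0.022), but not with an estimated correlation (adjusted p = 0.0907), and the exact permutation test of its mean did not pass (adjusted p = 0.074).

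Astrocyte genes did not differ at the list level. Of 16 general astrocyte markers none was called, with Aqp4 at 0.13 ± 0.08, Slc1a3 at 0.08 and S100b at 0.11 (camera adjusted p = 0.096). Of 13 reactive astrocyte markers 4 were tested and none was called (adjusted p = 0.207). Gfap, the intermediate filament of reactive astrocytes, was at 0.34 ± 0.22 (adjusted p = 0.850), with 3 of 9 PLX5622 libraries above the control mean. Without PLX5622 27, which held 166 counts, Gfap was at 0.14 ± 0.13. Cp was at 0.19 and Vim at 0.10. The A1 list, with 5 of 12 genes tested, did not pass (adjusted p = 0.762), with Srgn at -0.40, H2-D1 at 0.23 and Fkbp5 at 0.18. Neither did the A2 list, with 3 of 12 tested (adjusted p = 0.197), where Ptgs2 was at 0.43, Tm4sf1 at 0.08 and S100a10 at 0.02.

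Whether libraries with less residual microglial RNA held more reactive astrocyte RNA was asked within PLX5622. Pearson's r between the list means was -0.07 (exact p = 0.857, adjusted 0.887 over 6 relations) and Spearman's rho 0.17 (exact p = 0.678), and r was 0.48 without the 2 libraries farthest from the median. Within the controls r was 0.80 (exact p = 0.0059, adjusted 0.019), rho 0.88 (exact p = 0.0031) and r without the 2 farthest libraries 0.66. The difference between the diets was not tested.

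The remaining cell type lists were not called by camera, at adjusted p of 0.067 for oligodendrocyte precursors, 0.870 for myelinating oligodendrocytes, 0.118 for neurons in general, 0.362 for glutamatergic, 0.313 for GABAergic and 0.966 for striatal neurons. The mean log2 CPM of the precursor list was 5.15 ± 0.10 in controls and 5.28 ± 0.07 with PLX5622 (SD, n = 9 each), which passed the exact permutation test (adjusted p = 0.024). The summed CPM, 669 ± 40 and 684 ± 22, did not pass (exact p adjusted 0.488), and neither did camera with an estimated correlation (adjusted p = 0.105). Among precursor genes Cacng4 was at 0.32, Olig2 at 0.49 and Tnr at -0.09. Myelin gene Mbp was at 0.05 ± 0.15, Opalin at -0.25, Mobp at 0.30 and Cldn11 at 0.13. The synaptic gene Snap25 was at 0.04 ± 0.04, Uchl1 at 0.06, Nefm at 0.11 and Syp at 0.05. Nrn1, Neurod6 and Fezf2 were at 0.12, 0.15 and 0.15, Slc32a1, Npy and Dlx1 at -0.16, -0.14 and -0.20, and Ppp1r1b, Pde10a and Drd1 at 0.19, -0.13 and -0.27. Endothelial (adjusted p = 0.313), mural (0.347) and meningeal fibroblast (0.226) lists were not called, with Tek at -0.29, Slc2a1 at 0.16, Flt1 at -0.10, Myl9 at -0.13, Acta2 at -0.05, Col1a2 at -0.27, Slc13a4 at -0.31 and Dcn at 0.19. Red blood cell genes summed to 165 ± 59 CPM in controls and 218 ± 93 with PLX5622 (exact p adjusted 0.473), with Hbb-bt at 0.56 and Hbb-bs at 0.32. Choroid plexus markers summed to 12.5 ± 4.0 and 24.5 ± 10.8 CPM, 148 and 294 counts (exact p adjusted 0.020). Ttr, the only one tested, had 5.30 ± 3.26 and 15.5 ± 9.8 CPM and was at 1.49 ± 0.44 (log2, SE, edgeR adjusted p = 0.283). The difference in the sums thus rests mainly on Ttr.

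Lists of signalling and metabolism gave no other call in the fit without covariates. Of 20 genes of cytokines and Toll-like receptors only 5 were tested, with Tlr3 at -0.09 ± 0.18, Nfkb1 at -0.09 and Ikbkb at 0.08. Camera's adjusted p was 0.951 for these, and the rest of the list could not be assessed. Camera's adjusted p was 0.313 for antigen presentation (5 of 11 genes tested), with H2-K1 at 0.36 and Cd74 at -0.26. It was 0.096 for glutamate and GABA receptors, with Gabrb2 at -0.11 and Gria3 at -0.07, and 0.060 for glucocorticoid-responsive genes, with Zbtb16 at 0.17 and Tsc22d3 at 0.22. With the position of the animal number as a covariate, added after seeing the data, camera called the glucocorticoid list higher (adjusted p = 0.027), but not with an estimated correlation (adjusted p = 0.131). Without the covariate the adjusted p was 0.328 with an estimated correlation and 0.340 by the exact permutation test of its mean. Without a covariate camera's adjusted p was 0.118 for ethanol metabolism, with Acss2 at 0.21, Cat at 0.29 and Aldh1a1 at 0.14, and 0.067 for genes encoded in mitochondria, with mt-Nd2, mt-Nd4 and mt-Nd1 at -0.07, -0.06 and -0.05. For circadian genes it was 0.986, with Arntl at 0.30 (edgeR adjusted p = 0.067), Dbp at -0.26 and Per2 at 0.28. The median of that list was -0.03 while camera's direction was up. Of the proliferation list only Pcna, at 0.00 ± 0.19, was tested. At an unadjusted p under 0.05 there were 356 genes lower and 394 higher.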

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

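All tests in this part on the immediate-early and cholesterol genes, and the splits of the libraries, were chosen or written down after the result was seen. In 20 of 266 groups of 9 libraries, 1 library lay apart from the rest by Dixon's ratio at its 95% critical value. Chance flags about 1 in 20 groups, or 13.3 of 266 if the groups were independent, which genes of 1 library are not. In control 3 the values stood highest for Lyz2 (5.58 log2 CPM), H2-D1 (5.62), the antigen presentation list (mean 5.42) and the homeostatic microglia list (5.15), and lowest for Pdgfra (3.32). Control 10 was highest for Junb (5.18) and lowest for Gria3 (9.23). Within PLX5622, library 27 was lowest for Siglech (1.08), Hbb-bt (2.41), Hbb-bs (4.95) and the red blood cell list (mean 3.68). Library 35 was highest for Slc1a3 (9.29), S100b (7.85) and Tsc22d3 (6.45). Library 25 was lowest for Dcn (3.28) and the meningeal fibroblast list (3.26), library 26 for Fkbp5 (3.88), library 28 for Sqle (5.58), library 31 for Tek (3.70) and library 32 for Olig2 (2.95).

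Other splits of the 18 libraries into 9 and 9 were compared with the split by diet, 100 in all with the real one. A split and its mirror are the same, so each other split was counted by the larger of its 2 directions, lower or higher. For the 39 lower genes only 1 of 100, the real split, reached the count, with 32 the highest of the others. So few splits cannot exclude chance. The other splits also mix the diets unevenly, with 2 to 7 PLX5622 libraries on one side, so each keeps part of the diet difference. For the 5 higher genes 3 of 100 splits reached the count and the highest other was 32. The split that called 32 genes had 5 PLX5622 libraries on one side. A count this large points to some structure of the samples, and what that structure is was not tested. The counts of lists do not stand out: 35 of 100 splits called as many in either direction as the 4 lists lower. As many as the 3 lists higher were called in either direction by 58 of 100, with 8 the highest other in both. With an estimated correlation, 3 of 100 splits reached the 2 lists lower, 3 of 100 the 2 lists higher, and the highest other was 3. Camera's p with its preset correlation is likely too small for these libraries, though splits that keep part of the diet difference cannot settle this. The exact permutation p of a list's mean or sum needs no preset correlation. It takes the libraries as exchangeable, and mean and sum disagreed for the disease-associated microglial and oligodendrocyte precursor lists.

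The immediate-early list was 0.56 ± 0.15 (SE) higher in log2 CPM with PLX5622. Genes of the microglial and border macrophage lists and the other lower genes, 62 in all, lost 0.0782% of all counts. This alone would raise every other gene by 0.0011 on the log2 scale. Transcripts that microglia share with other cells are not in this share, so the rise from all lost microglial RNA could be larger. Such a rise would be alike in genes of other cells. The general neuron list had a median of 0.02 (log2) and the immediate-early list 0.60, which argues against a pure composition effect. A handling order or session tied to the animal number stays open. The lower of the correlations with the number within a diet was 0.86, and the diets occupy separate ranges of numbers, so diet and session cannot be told apart. A straight line at the control slope of 0.088 per number would put the diets 2.02 apart, more than observed, but a line over unused numbers is an assumption and excludes nothing. An effect of the diet on neuronal activity also stays open and may act together with handling.

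The cholesterol list was 0.26 ± 0.06 (SE) higher with PLX5622. Within the diets it changed by 0.03 ± 0.11 per unit of the myelinating oligodendrocyte list, which itself differed by 0.03 ± 0.14 between the diets (log2, SE). With both at 2 SE above their estimates oligodendrocyte content would give a difference of 0.077, below the observed one less 2 SE, which argues against it as the whole cause. The freed share of counts, 0.0011, leaves out transcripts that microglia share with other cells and sets no upper limit. The general neuron list, at a median of 0.02 (log2) against 0.23 for the cholesterol list, argues against a pure composition effect here too. With the immediate-early list as a covariate it was 0.14 ± 0.07, within 2 SE of 0 and not clearly below the unadjusted value. A source shared with the immediate-early genes, handling included, therefore cannot be told apart from an effect of the diet.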

How the results depend on the processing

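The covariate for the position of the animal number and the fit without control 8 and PLX5622 28 were chosen after seeing the data. The median log2 fold change of the homeostatic microglia list lay between -1.82 and -1.65 when each library was left out in turn, and at -1.73, -1.73, -1.73, -1.73 and -1.74 with other size factors, library size only, scaling without the microglial and mitochondrial lists, the number covariate and without control 8 and PLX5622 28. The count of lower genes, 39, ran from 38 to 50 over left-out libraries, and was 65 with DESeq2 (34 of the 39 among them), 92 with no filter on low counts, 8 with a mean of at least 50 counts (which tests 5767 genes) and 25 against a fold of 1.2. The count of higher genes, 5, was 20 with no filter. It was 0 with a mean of at least 50 counts (edgeR, 214 at an unadjusted p under 0.05), where 2 of the 5 were tested. It was 11 with 1 surrogate variable, 17 with the number covariate, 8 without control 8 and PLX5622 28, 0 at an adjusted p under 0.01, 10 at 0.10 and 0 against a fold of 1.2. It ran from 2 without control 2 or control 4 to 13 without PLX5622 25, and was 3 without control 3, PLX5622 34 or PLX5622 35 and 8 without control 8. In each fit listed the 5 genes kept a positive sign where tested. Lists called lower, 4, were 2 with an estimated correlation and 3 to 6 over left-out libraries. Lists called higher, 3, were 5 with 1 surrogate variable, and 2 without control 8 to 5 without PLX5622 25. The calls of disease-associated microglia and interferon genes ended with fry (adjusted p = 0.052 and 0.082), and those of interferon genes and CSF1R ligands ended without control 8 and PLX5622 28 (0.076 and 0.087). Thinning to the smallest library ended the call of disease-associated microglia (0.163). The interferon call also ended without control 8 (0.065) or PLX5622 34 (0.068), and that of CSF1R ligands without control 5 (0.058), control 8 (0.067), PLX5622 25 (0.103) or PLX5622 32 (0.075). The correlation of residual microglial with astrocyte expression was -0.57 with the general astrocyte list and -0.05 without Gfap, and neither passed. Without the 2 farthest libraries these were -0.89 and 0.42. The cause of these changes was not tested, apart from the number of genes that a filter leaves to test.

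Over 107 named genes and 1330 values, which take from the left-out libraries only the fits with the lowest and highest fold change of each gene, 1269 kept their sign and side of the threshold, 11 lost and 33 gained a call, and 17 changed sign, all in genes called in neither fit. Over all left-out libraries, 22 calls were lost among the 18 named genes called. Leaving out single libraries gave ranges of -0.069 to 0.062 for Csf1, -0.049 to 0.042 for Il34, -0.064 to 0.089 for Pdgfra, -0.023 to 0.12 for Mbp, -0.014 to 0.062 for S100a10, -0.20 to 0.016 for Acta2, -0.11 to 0.13 for Pcna and -0.028 to 0.060 for Ddx3y. Without control 8 and PLX5622 28 the values were 0.0057 for Il34, -0.030 for Pdgfra, 0.0063 for Trbc2, -0.023 for Tm4sf1, -0.018 for S100a10, 0.030 for Acta2 and 0.0072 for Nfkb1. Aldh1a1 was at -0.043 after thinning and Pcna at -0.0020 with DESeq2. No paired analysis was possible because the diets share no replicate number. At about 1 to 2 counts per CPM, the smallest change simulated was mostly below what these libraries could show, with 40% of such genes recovered.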

Other observations

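The genes and tests in this part were chosen after the values were seen. With the position of the animal number within its diet as a covariate, 34 genes varied with position (edgeR adjusted p under 0.05), 18 of them upward and 16 downward. Fitted within a diet alone, 4 genes were called on position in controls and 48 with PLX5622. Of the 18 upward, 7 stand on the immediate-early list. Arc, a synaptic immediate-early gene, changed by 0.18 ± 0.02 per position (log2, SE), Fos by 0.16 ± 0.02, Nr4a1 by 0.12 ± 0.02, Btg2 by 0.13 ± 0.02 and Egr4 by 0.10 ± 0.02, while Homer1 changed by 0.04 ± 0.01. Their differences between the diets without the covariate were 0.98, 0.88, 0.61, 0.69, 0.40 and 0.26, none called by edgeR (lowest adjusted p = 0.186). DESeq2 called Arc (adjusted p = 0.029) and Btg2 (0.049) and not Fos (0.142), Nr4a1 (0.162), Egr4 (0.404) or Homer1 (0.056). With the covariate they were called, at adjusted p of 1.8e-13 for Arc, 4.8e-07 for Fos, 4.3e-07 for Nr4a1, 0.00020 for Btg2, 0.022 for Egr4 and 0.0013 for Homer1. The covariate removes spread within a diet and not a difference between sessions. The labels do not say what the number stands for.

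Glucocorticoid-responsive genes also followed the animal number within PLX5622, with r = 0.87 (exact p = 0.00060, adjusted 0.016 over 54 relations), rho = 0.92 (exact p = 0.0013) and r = 0.82 without the 2 farthest libraries. In controls r was 0.17 (exact p = 0.670) and rho 0.27 (exact p = 0.4933). The difference between the diets was not tested. In the fit with position, camera called the immediate-early, glucocorticoid (adjusted p = 0.0014), cholesterol (0.0021), myelinating oligodendrocyte (0.0054) and circadian (0.031) lists upward with position, and the mitochondrial (0.0014) and glutamate and GABA receptor (0.0067) lists downward. With an estimated correlation only the immediate-early list was called (adjusted p = 5.8e-05), with the others at 0.087, 0.359, 0.721, 0.296, 0.296 and 0.374 in that order. For the cholesterol list within PLX5622 r was 0.64 (exact p = 0.066, adjusted 0.398 over 54 relations), rho 0.70 (exact p = 0.043, adjusted 0.292) and r 0.37 without the 2 farthest libraries. In controls r was 0.37 (exact p = 0.341) and rho 0.28 (exact p = 0.463).

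Several low-count macrophage and microglial genes, chosen after their values were seen, were lower with PLX5622. F13a1 had 81 counts in controls and 16 with PLX5622 (5.12-fold lower by mean CPM), Stab1 109 and 31 (3.47-fold), Gpr34 122 and 26 (4.91-fold) and P2ry13 101 and 26 (4.19-fold), with exact permutation p adjusted over 17 genes of 0.00023, 0.00042, 0.00023 and 0.00035. Lyve1, another border macrophage marker, had 13 and 9 counts (exact p adjusted 0.779), a difference that did not pass the test, while Cbr2, a further such marker, had 12 and 0 counts (exact p adjusted 0.0048). S100a8 and S100a9, neutrophil genes, had 131 and 90 and 152 and 91 counts. Of these 88 and 105 came from control 3, the library that also stood highest for Lyz2.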
